A study of Mus musculus with 2 samples.

How the data were processed

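The series holds 12 peak lists on mm10 from ATAC-seq of newborn mouse kidney: 3 for each of the 2 biological replicates and 6 for the series as a whole. Per the labels, DNA was fragmented by Nextera tagmentation, the library size range was 200 to 750 bp, and each replicate was a pool of male and female animals; that the pools are separate is given by their biological replicate numbers. Aligner, peak caller, the shift of reads for the transposase and the thresholds are not given in the sources used here. Per the file headers and the deposited descriptions, the replicated, pooled pseudoreplicated, IDR-thresholded and conservative lists were made from both replicates, and the pseudoreplicated, IDR-thresholded and IDR-ranked lists of a replicate from its own alignments (IDR, the irreproducible discovery rate, scores how well the ranks of peaks recur). The deposited rows give, per summit, a score, the peak caller's signal value, the −log10 of a p-value and of a q-value, and in the IDR-ranked lists the −log10 of the local and global IDR; these are the authors' values, and no deposited unit was rescaled. Signal was used to rank and describe regions within a list. The exceptions, which set deposited values of separately called lists side by side, are the rank correlation of shared regions, and in the closing section the test of depth and the comparison of signal per gene list at shared distal regions, which includes the proximal tubule test. The IDR values, and the q-values of the lists made from both replicates, were not used; they were taken out of the table of used columns after the data were examined, when it was found that no result drew on them. P53 had no hit and no ratio.

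No read counts were used, so depth per sample is unknown and no interval that needs it is given. The number of regions in a list moves with depth, and weak regions are the least reliable.

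Overlapping rows on the 21 assembled chromosomes were merged into regions, each represented by its summit of highest signal. Genes, exons and starts came from the GENCODE M21 basic annotation and sequence from GRCm38. A promoter region overlaps the 1 kb either side of any annotated start of any gene type. Lists were compared by overlap of at least 1 bp, and chance overlap by 100 shuffles within chromosomes whose region ends avoid assembly gaps. For each gene list, the share of members with a promoter region was placed among 10000 random lists of protein-coding genes matched on decile of promoter GC content, and the median number of distal regions from 50 kb upstream to 50 kb downstream of the gene among 10000 lists matched on decile of domain length; ties count as 0.5. Random lists were drawn with replacement from genes outside the list. Percentiles are descriptions, since genes are not replicates. The 21 lists covered nephron progenitor, podocyte, proximal tubule, loop of Henle and distal tubule, collecting duct and ureteric bud, stroma, endothelium, macrophage, erythroid, CAKUT, adrenal, liver, neuron, muscle, germ line, pluripotency, housekeeping, Hox paralogs 9 to 11, 12 and 13, and 1 to 4, and olfactory receptors; of the named symbols Ahsp did not match the annotation. Lists between replicates were compared at the same number of regions by an exact McNemar test with Benjamini-Hochberg adjustment, which a calculation made after the data were examined showed could not pass for any list.

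The 35 consensus sequences were searched on both strands within 75 bp of a summit. The background was 2 windows per summit, drawn from a larger pool of random windows off all regions in GC bins of 2%; 171 windows could not be matched, which left 85883, and mean GC was 53.7% at summits and 53.6% in the background. The corresponding background for promoter summits fell 10755 windows short and was not matched in GC, so promoter ratios to background are not reported and distal and promoter summits were compared directly. An alternative background, of windows 2 kb either side of each summit, was not matched on GC content. Ratios carry Katz 95% intervals and Fisher's exact test with Benjamini-Hochberg adjustment. Alignments to the mitochondrial genome and the search for other copies used BLAST+ 2.17.0; an alignment counted at 80% identity or more, and a copy at 95% identity over at least 50% of the region.

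The lists, sequences, tests, thresholds of 1.5 and 0.67 and most alternatives were fixed before the data were examined. The named genes rule, also fixed then, takes from each list the 3 members with the highest signal in their promoter or domain and up to 2 members without a promoter region in alphabetical order, the 10 densest domains, the 10 distal regions of highest signal, the 5 strongest IDR-thresholded regions per replicate that the other lacks, and sequences past a threshold; other names were chosen after their values were seen. Chosen after the data were available were the representative summit, the basic annotation, the background size and GC bins, the 2.5% tails, the bound of 0.1 for a change in correlation, the joined kidney and other-tissue sets, and the domain of Glis2 for the map. Another 2 analyses, a comparison of sequences in regions of 1 replicate alone matched on signal and a table of signal differences per sequence, were run and then removed, after their results were seen, because they compared deposited signals of separately called lists. Sequences within the domains of each gene list were also compared with those elsewhere, and no pair passed. The scripts were tested on simulated data: 35 of 35 planted sequences were detected and 0 unplanted ones called, and 3 of 50 unchanged lists exceeded the upper tail bound. Sequences were planted in random rather than genomic sequence, at a higher share than any had at distal summits. Power for rare sequences and false calls on genomic background were therefore not tested. Alternatives were other lists, windows, domains, overlaps, backgrounds and random lists, a −log10 q of at least 4, and each replicate alone; the comprehensive annotation, lists matched also on number of starts, and promoter shares at the same number of regions were added after the data were examined. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.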

Results

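Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in whole kidney of newborn mice of B6N strains (age 0 days). The mouse kidney is still forming nephrons at birth, so the tissue holds nephron progenitors beside maturing podocytes, tubules, collecting ducts, stroma and vessels. The series has 1 group with 2 biological replicates, each a pool of male and female animals; replicate 1 was pooled from 15 mice, and the number in replicate 2 is not given in the sources used here. With 1 group, the design holds no contrast between conditions: the values below describe the tissue, and the comparisons are between the 2 replicates and against random gene lists, shuffled regions or background sequence. Read depth is unknown, since only peak lists were used. A region is a set of overlapping rows of a list, and a region within 1 kb of an annotated transcription start is called a promoter region; all others are called distal.

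The authors' replicated list held 61899 regions with a median width of 469 bp, which covered 36.1 Mb or 1.36% of the mm10 genome. Replicate 1 had 56471 regions and replicate 2 had 39131, a ratio of 1.44. The replicated list, made from both replicates, was longer than either, so a region in it need not be in either replicate's own list. In the IDR-thresholded lists the numbers were 18673 and 13582, a ratio of 1.37.

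Promoters were the most enriched class of sites. Of the replicated regions, 30.5% were promoter regions, against 5.71% of regions shuffled within chromosomes (mean of 100 shuffles, highest 5.90%). The promoter share was 32.3% in replicate 1 and 41.5% in replicate 2 (mean 36.9% ± 6.45, SD, n = 2). Introns held 37.5% of the replicated regions and 40.3% of the genome, intergenic sequence held 27.7% and 52.5%, and exons held 4.28% and 2.91%. Promoter regions were wider than intronic ones (median 870 bp against 390 bp) and had a higher median signal (6.37 against 3.44, the authors' value per summit). In the shorter IDR-thresholded list, 57.2% of the regions were promoter regions. A promoter region was present at 14462 of 21911 protein-coding genes, or 66.0% (replicate 1, 64.7%; replicate 2, 61.5%; mean 63.1% ± 2.27, SD, n = 2).

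Genes of kidney cell types were next compared with genes of other tissues, using lists fixed before the data were examined. Lists of blood cells and of several other tissues had fewer open promoters than random lists matched on promoter GC content. A promoter region was present at 1 of 12 macrophage genes (Csf1r, the receptor of the macrophage growth factor), 3 of 11 erythroid genes, 1 of 12 adrenal genes (Chga, a granule protein of chromaffin cells), 5 of 12 neuronal genes, 2 of 12 muscle genes, 4 of 12 germ-line genes and 2 of 12 pluripotency genes. It was also present at 8 of 1134 olfactory receptor genes, or 0.705%. Each of these 8 lists lay in the lowest 2.5% of 10000 matched lists, at percentiles from 0 to 1.97. The liver list, with 2 of 12 promoters open, lay at percentile 2.79. With either replicate's own list only 1 of 11 erythroid genes had a promoter region, and in replicates 1 and 2 it was 0 and 1 of 12 muscle genes and 3 and 2 of 12 germ-line genes. With each replicate's own list 7 of the 8 lists stayed in the lowest tail, and the neuronal list left it in both.

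In the replicated list, promoters of the kidney lists were mostly open, though no list stood in the highest 2.5% of GC-matched lists. The stromal list did so in the pooled pseudoreplicated list and, with the CAKUT list, in the list of replicate 1, and no kidney list did in that of replicate 2. Ties count as 0.5, so in the replicated list the fully open podocyte list was at the highest percentile it could reach. It could not enter the highest tail there, whatever its promoters. The same held for the housekeeping list and Hox groups 9 to 11. All 13 podocyte genes had a promoter region (percentile 92.4), as did 11 of 14 proximal tubule genes (percentile 92.0), 10 of 13 stromal genes (percentile 88.8), 12 of 14 nephron progenitor genes (percentile 59.1), 7 of 12 genes of the loop of Henle and distal tubule (percentile 57.9) and 12 of 14 collecting duct and ureteric bud genes (percentile 53.6). The last 3 lists therefore sat near the middle of matched lists. Among the genes counted, Meox1 (nephron progenitor), Nphs2 (podocyte), Miox (proximal tubule) and Trpv5 (distal tubule) had a promoter region in neither replicate's own list. Of 21 genes mutated in congenital anomalies of the kidney and urinary tract (CAKUT), 20 had a promoter region (percentile 96.9); Bmp4 had none. The list shares 8 of its 21 genes with other lists, and the nephron progenitor list shares 7 of 14. The endothelial list had 8 of 13 promoters open (percentile 25.1) and the housekeeping list 14 of 14 (percentile 97.0). The podocyte share was 92.3% in replicate 1 and 61.5% in replicate 2 (mean 76.9% ± 21.8, SD, n = 2), and the stromal share 84.6% and 53.8% (mean 69.2% ± 21.8, SD, n = 2). Joined into one set, which was done after the data were examined and without matching on GC, 63 of 78 kidney genes (80.8%) and 16 of 72 genes of adrenal, liver, neuron, muscle, germ line and pluripotent cells (22.2%) had a promoter region, a difference of 58.5 percentage points. The kidney genes joined were those of the nephron, collecting duct and stromal lists. The endothelial (8 of 13 open) and macrophage (1 of 12) lists, of cells also present in kidney, were in neither set, and the difference depends on that choice. In the IDR-thresholded list most kidney promoters had no region: the numbers were 34 of 78 (43.6%) and 7 of 72 (9.72%), a difference of 33.9 points, and the podocyte and collecting duct lists lay in the lowest tail of matched lists.

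**Figure D1:**
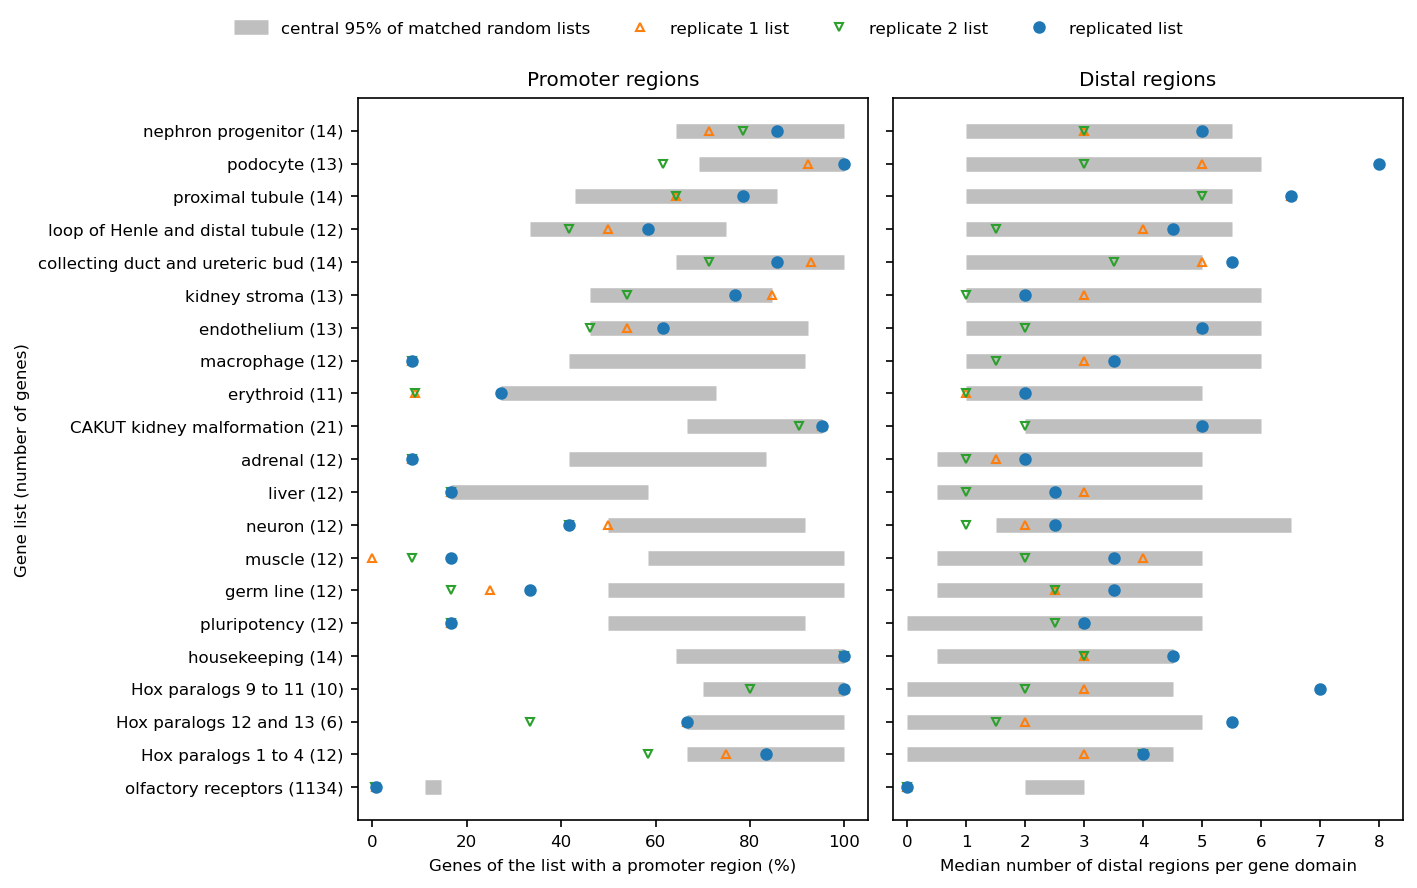
Share of each list's genes with a promoter region (left, percent) and median number of distal regions per gene domain (right) for the 21 gene lists. Filled circles give the replicated list, open triangles each replicate's own list, and grey bars the central 95% of 10000 random lists matched on promoter GC (left) or domain length (right); the olfactory receptor list lies below its bar in both panels, and the podocyte list at 8 distal regions lies above its bar on the right.

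Distal regions were dense around genes of 3 kidney epithelial lists. The median number of distal regions from 50 kb upstream to 50 kb downstream of the gene was 8 for podocyte genes (percentile 99.9 among lists matched on domain length), 6.5 for proximal tubule genes (percentile 99.4) and 5.5 for collecting duct and ureteric bud genes (percentile 98.9), against 3 over all protein-coding genes. The medians per replicate were 5 and 3 for podocyte, 6.5 and 5 for proximal tubule, and 5 and 3.5 for collecting duct genes. Proximal tubule and collecting duct were also in the highest 2.5% with each replicate's own list, whereas podocyte was not in either. Nephron progenitor genes had a median of 5 (percentile 95.5; replicates 3 and 3), CAKUT genes 5 (percentile 80.9; replicates 5 and 2), endothelial genes 5 (percentile 85.3; replicates 5 and 2), loop of Henle and distal tubule genes 4.5 (percentile 85.5; replicates 4 and 1.5) and stromal genes 2 (percentile 19.7; replicates 3 and 1). Housekeeping genes had 4.5 (percentile 96.7; replicates 3 and 3). Medians of most other lists were also lower in replicate 2 than in replicate 1. The macrophage list had a median of 3.5 (percentile 66.2), muscle 3.5 (percentile 82.2), germ line 3.5 (percentile 73.6), pluripotency 3 (percentile 72.1), liver 2.5 (percentile 47.8), neuron 2.5 (percentile 19.9), adrenal 2 (percentile 35.4), erythroid 2 (percentile 33.1) and olfactory receptors 0 (percentile 0). With 100 kb domains the proximal tubule list left the highest tail, and in the IDR-thresholded list it was the only one of the 5 lists that stayed there. The housekeeping list, outside that tail in the replicated list, was in it in the pooled pseudoreplicated list, the IDR-thresholded list and the list of replicate 2. A high distal count was thus not confined to kidney lists.

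The nephron progenitor genes of highest signal had it at their promoters, whereas other members, such as Osr1 (promoter 4.48, distal 7.84) and Sall1 (5.54 and 6.84), had a stronger distal region. Itga8, an integrin needed for ureteric bud outgrowth, had a promoter signal of 8.58, Cited1 8.21 and Six2, the factor that maintains the progenitors, 7.96; Crym and Tmem100 had no promoter region. Among podocyte genes the highest signals were at a distal region of Clic5 (9.96, chromosome 17, 44239093 to 44240079), at a distal region of Synpo, which encodes the actin-binding protein synaptopodin (9.87, chromosome 18, 60605972 to 60606829), and at the promoter of Magi2 (9.55). Among proximal tubule genes they were at a distal region of Cubn (10.5, chromosome 2, 13371907 to 13372860), which encodes the endocytic receptor cubilin, and at the promoters of Lrp2 (10.3), which encodes megalin, and Gatm (9.92). Slc13a1 and Slc22a8 had no promoter region in the replicated list, and the domain of Slc22a8, an organic anion transporter, held 10 distal regions. Calb1, a calcium-binding protein of the distal tubule, had a promoter signal of 12.4. Umod, which encodes uromodulin, had no promoter region but 5 distal regions, the strongest at 9.04, and Trpm6 reached 7.78 at a distal region; Cldn16 and Pvalb had no promoter region. In the collecting duct list, the domain of Avpr2, the vasopressin receptor gene, held a distal region of signal 13.4, and Gata3 had a promoter signal of 10.8 and Wnt11 a distal signal of 8.30; Atp6v1g3 and Avpr2 had no promoter region. Stromal genes reached 9.54 at a distal region of Col1a1, 8.21 at a distal region of Meis1 and 7.85 at the promoter of Foxd1, a factor of stromal progenitors, while Dcn and Lum had no promoter region. In the CAKUT list the highest signals were 14.3 for both Trap1 (distal) and Dstyk (promoter), and 11.8 for Slit2 (distal). These absences of a promoter region refer to the replicated list. The list of replicate 1 had one at Avpr2 and at Dcn, and that of replicate 2 had one at Pvalb.

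In the endothelial list the highest signals lay at distal regions of Plvap (9.62), Tie1 (7.04) and Tek (6.99), and Cdh5 (except in the list of replicate 1) and Emcn had no promoter region. Macrophage genes showed the same arrangement, with distal signals of 12.8 near Tyrobp, 8.44 near Cx3cr1 and 7.65 near Csf1r, and no promoter region at Adgre1 or C1qa. The first 2 of these regions lay 40067 bp and 65984 bp from a start of the gene. The third was also the strongest distal region in the domain of the stromal gene Pdgfrb. Distal regions were assigned by position only, so none is shown to act on the gene named. Among erythroid genes Klf1 had a promoter signal of 7.70, and distal regions reached 7.12 near Slc4a1 and 5.97 near Hba-a1; Alas2 and Epb42 had no promoter region. The adrenal list reached 9.90 at a distal region near Nr5a1, 4.61 near Cyp11a1 and 4.35 near Chga, and Cyp11a1 and Cyp11b1 had no promoter region. The liver list reached 8.51 near Ahsg, 7.57 at the promoter of Fga and 7.20 near Apoa1, with no promoter region at Ahsg or Alb. Neuronal promoters of high signal were those of Snap25 (12.2), Elavl4 (10.3) and Syt1 (7.99), whereas Dcx and Gad1 had none. Muscle genes reached 7.08 near Mb, 5.75 near Myh3 and 5.44 near Acta1, and neither Acta1 nor Mb had a promoter region. Germ-line genes reached 10.5 near Mael, 10.3 at the promoter of Dazl and 7.17 near Tex101, with none at Ddx4 or Mael. Of the pluripotency list, Tfcp2l1, which is also a factor of the collecting duct, had a promoter signal of 10.4, and the same distal region of signal 7.37 lay in the domains of Dppa3 and Nanog; Dppa3 and Dppa4 had no promoter region. Housekeeping promoters reached 15.5 at Eef1a1, 15.2 at Pgk1 and 13.1 at Sdha. The highest signals in olfactory receptor domains were 10.4 near Olfr1358 and 10.1 near Olfr286 and Olfr287, and Olfr1 and Olfr10 had no promoter region.

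Most promoters of Hox genes, which set position along the body axis, were open in the replicated list. All 10 genes of paralog groups 9 to 11, the groups used in kidney development, had a promoter region (percentile 78.8), as did 4 of the 6 genes of groups 12 and 13 (percentile 3.45; 4 in replicate 1 and 2 in replicate 2) and 10 of the 12 genes of groups 1 to 4 (percentile 41.4). Groups 12 and 13 were in the lowest promoter tail in the list of replicate 2 and, with groups 1 to 4, in the IDR-thresholded list. The median number of distal regions was 7 for groups 9 to 11 (percentile 99.995; replicates 3 and 2), 5.5 for groups 12 and 13 (percentile 98.8; replicates 2 and 1.5) and 4 for groups 1 to 4 (percentile 93.6; replicates 3 and 4). The order of these lists was not kept in the replicates and was not tested: groups 9 to 11 and groups 12 and 13 were in the highest tail in neither replicate, and groups 1 to 4 were in it in replicate 2. Genes of a cluster share their domains: the same distal region of signal 5.72 (chromosome 15, 102998672 to 102999900) was the strongest for Hoxc9, Hoxc10, Hoxc11 and Hoxc4. Hoxc13 had a promoter signal of 5.92, Hoxb4 5.50 and Hoxd1 5.50, and distal signals were 5.76 near Hoxa13 and 4.41 near Hoxb13; Hoxb13, Hoxc12, Hoxa2 and Hoxb3 had no promoter region.

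The densest domain was that of Pam16 on chromosome 16, with 19 distal regions or 17.5 per 100 kb, followed by Trim8 on chromosome 19 with 20 (17.4 per 100 kb). In the replicates' own lists, Pam16 had 13 and 8 and Trim8 had 15 and 12, so that Trim8 ranked above Pam16 in both. Next came Glis2, a zinc finger factor mutated in nephronophthisis, whose domain overlaps that of Pam16 and held 21 (16.1 per 100 kb). Of the others, Smug1 had 18 (15.8 per 100 kb), Sh2d6 17 (15.7 per 100 kb), Irf2bpl 16 (15.4 per 100 kb) and the homeobox gene Uncx 16 (15.3 per 100 kb). The other 3 of the 10 densest, 3110040M04Rik, Gm47995 and Gm47996, neighbour one another on chromosome 1 between 151198448 and 151211072 and had 16, 15 and 15.

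**Figure D2:**
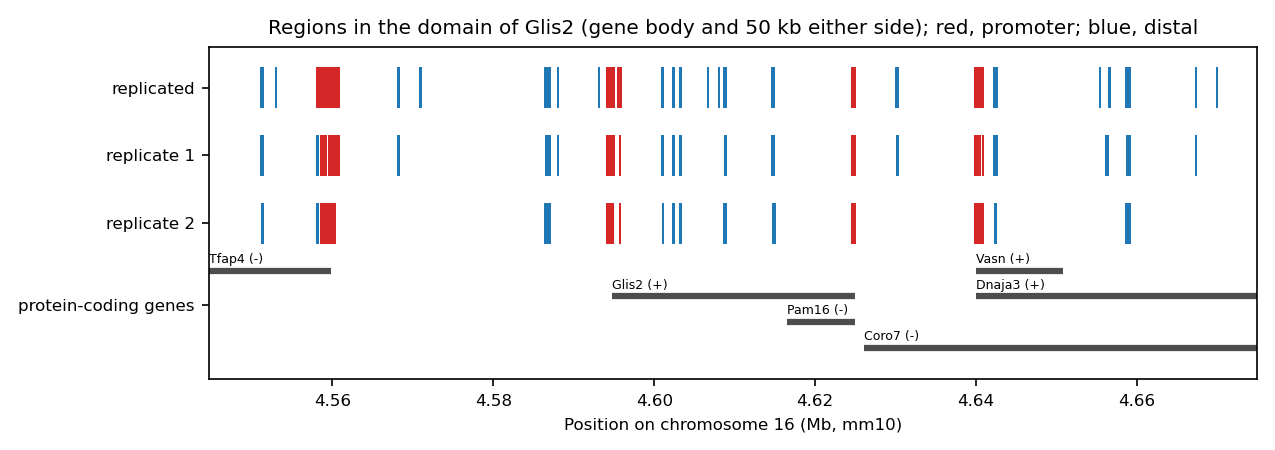
Regions in the domain of Glis2 (chromosome 16, 4544713 to 4674924, mm10) in the replicated list and in each replicate's own list, with position in Mb on the horizontal axis, promoter regions in red, distal regions in blue and protein-coding genes with their strand below. The replicated list held 21 distal regions in the domain, replicate 1 held 15 and replicate 2 held 10.

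Consensus sequences of many transcription factors, among them HNF4, HNF1 and CTCF, were enriched at distal summits. Of 35 consensus sequences fixed before the data were examined, 23 were found at over 1.5 times their share in GC-matched windows away from all regions with an adjusted p under 0.05, and 1, SOX, at under 0.67 times (Fisher's exact test, two-sided, Benjamini-Hochberg over 35; summits are not replicates). The sequence of CTCF, a factor that anchors chromatin loops, was at 4.26% of 43027 distal summits against 0.121% of background windows, a ratio of 35.2 (95% interval 28.9 to 42.8; replicate 1, 27.2; replicate 2, 33.4). The HNF4 sequence, read by regulators of the proximal tubule, was at 1.01%, a ratio of 6.70 (5.51 to 8.15; replicates 4.92 and 8.41). The HNF1 sequence was at 75 summits and 1 background window, a ratio of 150 with an interval of 20.8 to 1077. That ratio fell to 13.04 against flanking windows, which were not matched on GC content. The PAX2 and PAX8 sequence was at 30 summits, a ratio of 6.65 (3.16 to 14.0). The sequence of SIX2 and its relatives had a ratio of 2.76 (2.19 to 3.48), the shared WT1 and EGR sequence 2.62 (2.06 to 3.33), the sequence of the Wnt effectors TCF and LEF 2.07 (1.73 to 2.48), that of the stromal and podocyte factor TCF21 and of TWIST 2.02 (1.79 to 2.29), that of the endothelial factors ERG and FLI 2.40 (2.03 to 2.83) and FOX 2.00 (1.84 to 2.17).

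AP1 was at 6.16% of distal summits, a ratio of 2.69 (2.54 to 2.85), and TEAD at 7.43%, a ratio of 1.84 (1.76 to 1.93). The other sequences over 1.5 included rare ones: NFI (39 summits, 15.6; replicates 61.9 and 8.38), RFX (63, 7.40; replicates 13.6 and 13.1), REST (29, 7.24; replicates 14.5 and 3.42), MAF (11, 5.49; replicates 5.49 and 2.66), NRF1 (32, 3.99; replicates 3.50 and 4.99), HOX9 to 11 (36, 3.27; replicates 3.13 and 1.69) and MEF2 (92, 2.21; replicates 3.25 and 2.13). The rest were ETS (185, 2.06), SP and KLF (850, 2.01), GRHL and TFCP2L1 (272, 1.59) and ERR (202, 1.52). Of the 11 sequences not called, GATA had a ratio of 0.826, TFAP2 1.15 and POU 1.43. SOX had a ratio of 0.634 (0.528 to 0.762). The background was matched on GC content but not on soft-masked repeats, which made up 11.7% of distal regions and 36.4% of the genome. What repeats did to these ratios was not tested. Every call was kept in the list of replicate 1. ERR, HOX9 to 11, MAF and HNF1 were not called in the list of replicate 2, where HNF1 had 43 summits and 0 background windows and so no ratio. ERR and HOX9 to 11 were not called in the IDR-thresholded list, nor were PAX2 and PAX8 (12 summits) and MAF (1 summit), which had 0 background windows there and so no ratio. Calls were also lost for ERR, FOX, GRHL and TFCP2L1, MAF, MEF2, and TCF and LEF against windows flanking the summits, where the ratio of MEF2 turned below 1, to 0.903. Those windows were not matched on GC content, so these losses can also reflect a difference in GC.

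**Figure D3:**
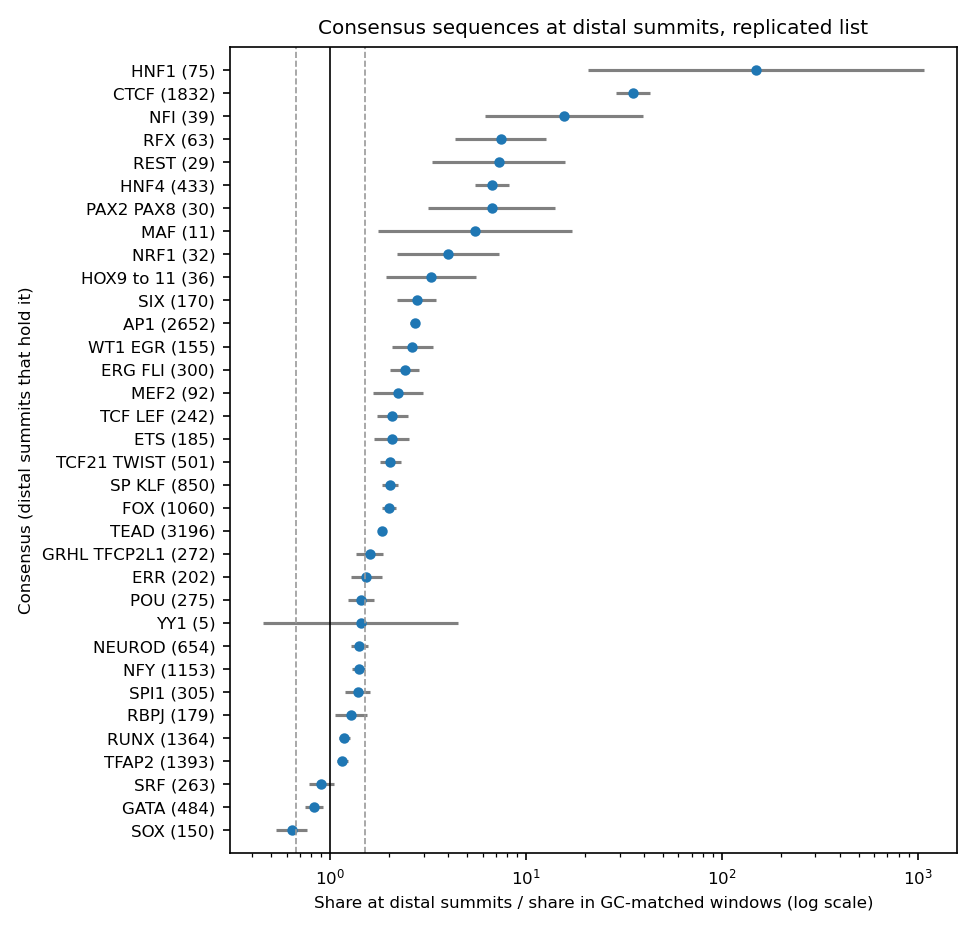
Ratio of the share of distal summits with each consensus sequence to the share of GC-matched background windows, on a log axis, in the replicated list; the number of distal summits that hold the sequence is in brackets. Points are ratios, lines 95% intervals, and dashed lines mark 1.5 and 0.67; CTCF lies at 35.2 and SOX at 0.634, and P53, with no hit, is not drawn.

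Distal and promoter summits carried different sequences. Compared directly, 16 sequences were at over 1.5 times the share of promoter summits and 9 at under 0.67 times, with an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg over 35). More frequent at distal summits were CTCF (ratio 3.49, 3.05 to 4.00), TCF and LEF (3.32, 2.29 to 4.79), HNF4 (3.06, 2.35 to 3.99), TCF21 and TWIST (3.01, 2.36 to 3.85), AP1 (2.47, 2.24 to 2.72) and TEAD (2.11, 1.94 to 2.29). Less frequent were the general promoter sequences of YY1 (0.0217), NRF1 (0.0872), ETS (0.0992), SP and KLF (0.152) and NFY (0.259), and also the WT1 and EGR sequence (0.402). These 2 classes of summit differ in GC content (53.7% against 64.1%), for which this comparison was not matched.

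Between the replicates, 56.7% of the regions of replicate 1 overlapped a region of replicate 2, and 82.8% the other way, against 1.78% and 2.55% for shuffled regions. With both lists limited to the 39131 regions of highest signal the shares were 71.0% and 72.8%. Promoter regions recurred more often than distal ones: 82.5% against 44.4% of replicate 1 regions, and 94.3% against 74.5% of replicate 2 regions. They were also wider and of higher signal, and this comparison was matched on neither. In the highest decile of signal 99.96% and 100% of the regions recurred, and in the lowest 19.98% and 51.0%. Across the 32032 shared regions the signals of the replicates had a Spearman correlation of 0.832 and a Pearson correlation of log signal of 0.861; regions are not independent replicates.

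**Figure D4:**
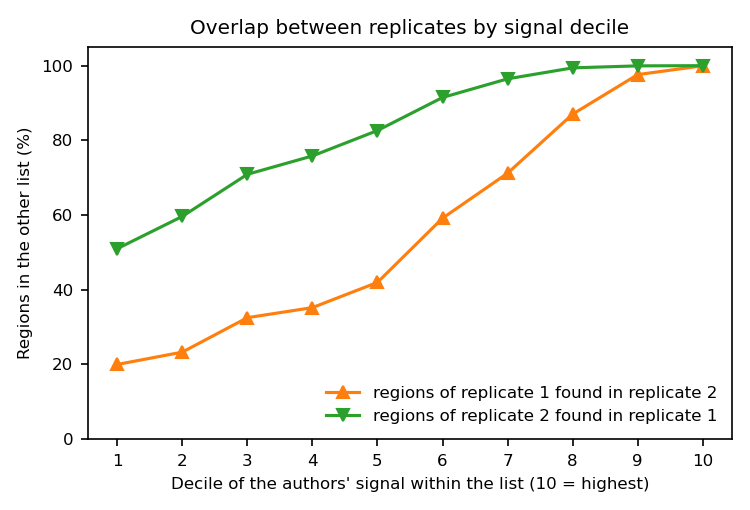
Share of each replicate's regions that overlap a region of the other replicate (percent, vertical axis) by decile of the authors' signal within its own list (horizontal axis). Triangles pointing up are replicate 1 and triangles pointing down replicate 2; the shares run from 19.98% to 99.96% for replicate 1 and from 51.0% to 100% for replicate 2.

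At 39131 regions each, 12770 protein-coding genes had a promoter region in both replicates, 532 in replicate 1 alone and 697 in replicate 2 alone. The widest gap was in stromal genes, open at 11 of 13 in replicate 1 and 7 of 13 in replicate 2, followed by podocyte genes at 11 and 8 of 13 and genes of Hox groups 9 to 11 at 6 and 8 of 10. With the full lists the gap of these Hox genes turned the other way, to 10 and 8 of 10. Whether the lists differ could not be decided: no list had more than 6 discordant genes, so that the lowest adjusted p an exact McNemar test could reach was 0.328. Of the IDR-thresholded regions, 891 of 18673 in replicate 1 and 53 of 13582 in replicate 2 overlapped no region of the other replicate's longer list. The strongest in replicate 1 had a signal of 10.4 and lay in an intron of Dcaf6 (chromosome 1, 165371060 to 165371362). The next 4 were on chromosome 11 (93762979 to 93763723, signal 10.1, intergenic, nearest start Utp18), chromosome 12 (40247937 to 40248425, signal 10.1, in an intron of Ifrd1), chromosome 10 (55335940 to 55336369, signal 9.87, intergenic, nearest start Msl3l2) and chromosome 3 (138198210 to 138198482, signal 9.68, intergenic, nearest start 4930579F01Rik). In replicate 2 they were on chromosome 16 (91534561 to 91534767, signal 10.1, intergenic, 12405 bp from Ifngr2), chromosome 13 (22015611 to 22016109, signal 8.69, in an intron of Gm11290, nearest start Prss16), chromosome 3 (28658404 to 28658692, signal 7.65, in an intron of Tnik, 39371 bp from the glucose transporter gene Slc2a2), chromosome 7 (29829859 to 29830135, signal 7.45, in an exon of Zfp790) and chromosome 4 (85767725 to 85767970, signal 7.17, in an intron of Adamtsl1).

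The 10 distal regions of highest signal were 246 to 489 bp wide, and 5 of them contained sequence that aligned to the mitochondrial genome. The strongest (58.2) was on chromosome 2 (69355469 to 69355735, intergenic, 12986 bp from Abcb11), with 48.3% of its length aligned at up to 100% identity. The second (57.2) was on chromosome X (143482935 to 143483180, intergenic, 35531 bp from Pak3) and did not align. Regions on chromosome 10 (96077546 to 96077953, signal 47.2, nearest coding start Gm5426), chromosome 5 (60042708 to 60043150, 44.8, nearest G6pd2), chromosome 6 (9889878 to 9890225, 29.9, nearest Nxph1) and chromosome 12 (97061368 to 97061856, 29.4, nearest Galc) aligned over 86.3%, 86.2%, 89.1% and 74.6% of their length. Those on chromosome 2 (3964420 to 3964690, 41.1, nearest Frmd4a), chromosome 16 (17222195 to 17222580, 32.9, nearest Hic2), chromosome 4 (20191761 to 20192037, 29.1, in an intron of Nkain3) and chromosome 17 (70963583 to 70963966, 28.7, in an intron of Gm26561) did not align. All 10 were present in both replicates.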

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

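The IDR-ranked lists, which entered no comparison of the report, hold regions that the pseudoreplicated lists leave out; they were examined only after the data were seen. In replicate 1, 1880 ranked regions on the chromosomes were absent from the pseudoreplicated list and 167 rows lay on unplaced scaffolds. In replicate 2 the numbers were 1280 and 151. Most were weak, with a median −log10 p of 4.15 and 4.13. Those with a −log10 p of 100 or more were few, 35 in replicate 1 and 32 in replicate 2, and each overlapped a left-out region of the other replicate. The strongest had a −log10 p of 7997 in replicate 1 and 4967 in replicate 2 and was the same site in both (chromosome 1, 24611586 to 24616162 in replicate 1). Its whole length aligned to the mitochondrial genome, at up to 99.956% identity.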

How the results depend on the processing

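No paired analysis was possible because the design has 1 group. With each replicate alone, the promoter share of regions ranged from 32.3% to 41.5%, the share of genes with a promoter region from 61.5% to 64.7%, the joined kidney minus other-tissue difference from 43.5 to 56.2 points, the number of lists in the highest promoter tail from 1 (housekeeping, replicate 2) to 3 (stroma, CAKUT and housekeeping, replicate 1; 0 in the replicated list), and the number in the highest distal tail from 2 to 4 (5 in the replicated list). The IDR-thresholded lists hold fewer regions: 18673 and 13582 for the replicates, a promoter share of 57.2% (conservative list 58.2%), 55.5% of genes with a promoter region (conservative 55.0%), and a joined difference of 33.9 points. In that list 14 gene lists were in the lowest promoter tail, among them podocyte and collecting duct, 1 was in the highest, 2 were in the highest distal tail and 0 in the lowest. The highest promoter tail held 1 list (stroma) in the pooled pseudoreplicated list, 4 without matching on GC, and 1 (housekeeping) when matched also on number of starts, an alternative added after the data were examined. The highest distal tail held 2 lists with 100 kb domains, and the lowest held 0 with 10 kb domains. At the same number of regions, also added afterwards, the promoter share was 38.7% in replicate 1 and 41.5% in replicate 2 (mean 40.1%), a gap of 2.79 points, so most of the gap between their full lists went with list length. Against flanking windows, the ratios of MEF2, a called sequence, and of POU and RUNX turned below 1, to 0.903, 0.678 and 0.822. Flanking windows were not matched on GC content, so every ratio to them can also reflect a difference in GC. SRF, under 1 in the replicated list, rose to 1.49 in the IDR-thresholded list, 1.02 and 1.04 with narrower and wider windows, and ranged from 0.951 to 1.04 with a replicate left out; YY1 ranged from 0.666 to 2.33 with a replicate left out and reached 2.39 with wider and with flanking windows. Apart from the smaller number of regions, the cause was not tested. Overlap between replicates (69.1% to 79.6%, mean of both directions), rank correlation (0.832 to 0.874) and the number of enriched sequences (21 to 25) stayed within their bounds under the alternatives run. The bound for overlap was 18.4 points, the SD of the 2 directions (56.7% and 82.8%). At equal numbers of regions the directions were 71.0% and 72.8%. The bound thus mostly reflects list length, and staying within it says little about stability. Between 17 and 23 of the 23 enriched sequences were shared with each alternative. Of single percentiles, 65 promoter and 60 distal values moved by more than the spread between replicates and 61 and 66 did not; of single sequence ratios, 178 kept their side of 1 and of an adjusted p of 0.05, 13 lost and 2 gained the p, and 8 changed side of 1, but size varied within the same side, as for HNF1 (13.04), NRF1 (15.3), SP and KLF (5.28), WT1 and EGR (6.45) and TFAP2 (2.64) against flanking windows and NFI (61.9) and REST (14.5) without replicate 2. The unknown depth limits all counts of regions.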

Other observations

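The pattern of HNF4 sequences between replicates and the test of depth were chosen after the values they concern had been seen; the other tests were written before their results. Promoter GC content went with open promoters: 3.29% of genes in the lowest GC decile had a promoter region against 95.9% in the highest. Autosomes held 25.4 regions per Mb, chromosome X 6.37 and chromosome Y 0.170. On chromosome Y, 3 of 183 protein-coding genes had a promoter region, Eif2s3y, Uty and Ddx3y, each in both replicates, which are pools of both sexes. Soft-masked repeats made up 11.7% of distal regions and 36.4% of the genome. The CTCF sequence was at 2.73% of distal summits in the lowest decile of signal and at 5.65% in the sixth decile, but at 3.05% in the highest decile and at 1 of the 100 strongest. HNF4 ran from 0.502% in the lowest to 1.42% in the highest decile, and was at 0 of the 100 strongest. At shares this low, 100 regions are too few for either count to show a departure from the highest decile.

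In the lists of these 2 libraries, some sequences differed in share between the distal regions found in 1 replicate alone, by an adjusted p over regions, which are not replicates, and without the bounds of 1.5 and 0.67 used in the report. HNF4 was at 83 of 5832 such regions of replicate 2 (1.42%) and 119 of 21242 of replicate 1 (0.560%). The ratio was 2.54 (95% interval 1.92 to 3.36, Fisher's exact test, adjusted p = 1.5e-08 over 35 sequences). AP1 (ratio 0.730), TEAD (0.723), FOX (0.708) and the ERG and FLI sequence (0.517) were more frequent in replicate 1. Of these only the last is past those bounds in the full lists. With equal numbers of regions the adjusted p stayed under 0.05 for all 5, and SP and KLF (1.53) and TCF21 and TWIST (0.668) joined them. There HNF4, SP and KLF, TCF21 and TWIST, TEAD (0.634), AP1 (0.669) and the ERG and FLI sequence (0.533) were past the bounds. Only FOX (0.713) was not. HNF4 was singled out for its size in the full lists, and it did not stand out from the ERG and FLI sequence with equal numbers. Each side is 1 library, so the intervals leave out the variation between libraries and no difference between kidneys is shown. A longer list reaching further into weak regions accounts for part at most: with equal numbers the HNF4 ratio fell to 1.86 but its interval, 1.39 to 2.48, stayed above 1, and after matching on GC content it was 2.52. A larger share of proximal tubule cells in replicate 2 had no evidence for it: at shared distal regions the proximal tubule list's signal difference lay at percentile 29.4 of matched lists, below the bound of 75 set beforehand against it, but this was not taken as an exclusion, a decision made after the value was seen, because 6 of 13 genes lay above 0 and the signals come from separately called lists.

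Replicate 1 had 1.44 times the regions of replicate 2. If deeper sequencing were the cause, −log10 p should be higher in replicate 1 at regions of equal signal; the median ratio was 1.19 (quartiles 1.09 and 1.31, 5167 regions), between the bounds set against it (1.1) and for it (1.2). A different mix of cells was also left undecided, since the test of the gene lists had too few discordant genes to pass. The widest gap between the replicates at the same number of regions was 30.8 points, over the 10 points set as the limit for excluding it. With lists this short that limit was easily exceeded: 1 gene of Hox groups 12 and 13 made a gap of 16.7 points. Exceeding it therefore does not count for a different mix. By the signal difference at shared distal regions (replicate 2 minus replicate 1, log2), the collecting duct list lay outside the central 95% of its matched lists, at −0.165 (percentile 0.75). It was the only one of 19 lists compared to do so, where about 1 is expected by chance, and it was picked after its value was seen and comes from separately called lists; the liver list and Hox groups 12 and 13 had too few genes to be compared. Depth and cell mix cannot be told apart here, since read numbers are unknown and the lists have few genes.

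For the 10 distal regions of highest signal, nuclear copies of mitochondrial DNA that collect mitochondrial reads were tested as a source, without a decision. Over at least 50% of their length, 4 of the 10 aligned to the mitochondrial genome, against 1 of 1000 random distal regions, which is between the bounds set beforehand (most of the 10, or 3 or fewer); 1 more aligned over 48.3%, and the other 5 not at all, so the explanation cannot hold for those. Near-identical copies elsewhere on the chromosomes, over at least 50% of the region, were found for 2 of the 10 and for 2 of 100 random regions. The 2 of the 10, on chromosomes 5 and 6, were among those that aligned to the mitochondrial genome. For the other 8 this argues against near-identical copies of that length on the chromosomes as the cause. Shorter copies, and copies on unplaced scaffolds or missing from the assembly, would not be seen. What raised the signal at the 5 regions without mitochondrial sequence was not tested further.

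Adrenal tissue attached to the kidney was tested as a source of signal. The adrenal list lay at percentile 0.005 for promoters and 35.4 for distal regions, both under the 50 set beforehand as counting against it. None of the genes named beforehand for it, Cyp11a1, Cyp11b1, Star, Mc2r, Th and Dbh, had a promoter region in the replicated list or in either replicate. This was not taken as an exclusion, a decision made after the values were seen: the macrophage list, of a minor cell type of the kidney, lay at promoter percentile 0, so a low percentile does not exclude a small share of cells. Chga had a promoter region in both replicates, and the domain of Nr5a1 held 5 distal regions (9 and 5 in the replicates), the strongest at 9.90. A small share of adrenal cells was left undecided.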
